A study of Homo sapiens with 46 samples.

How the data were processed

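RNA was sequenced from 46 samples in 14 groups. MDA-MB-231 breast cancer cells and U87MG glioblastoma cells received the antisense oligonucleotide ASO-1570 or a control oligonucleotide at 200 nM or at 50 nM for 48 hours, or an siRNA against TRA2B or a control siRNA at 10 nM for 48 hours. Each of these 12 groups held 3 libraries. The MDA-MB-231 samples of the 50 nM and siRNA experiments carry a glioblastoma cell type label, which conflicts with their sample names and cell line label, and they were analysed as MDA-MB-231. The last pair of groups came from a breast cancer patient-derived xenograft (PDX), a human tumour grown in mice, which was injected with either oligonucleotide at 50 mg per kg on 3 days a week for 4 weeks, with 5 tumours per group. Per the labels, libraries were made with a stranded mRNA kit and read as pairs of 151 bases.

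The deposited gene tables hold raw counts, whole numbers per Ensembl gene and library that were not scaled to library size. Per the submitters' processing notes, reads were checked with FastQC and MultiQC, trimmed with Trimmomatic, aligned with STAR to the human genome (GRCh38, also called hg38) and quantified with StringTie; versions, counting options and the annotation release were not stated. The deposited splicing tables hold the percent spliced in (PSI) of each splicing event and library as a fraction from 0 to 1. Per the file names these came from rMATS, with no version or settings given. No read counts stand behind the PSI values, so the depth of each event is unknown and no counting interval is given for PSI. The deposit also held pooled copies of the 200 nM tables, which were identical to them and were left out.

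The strand used in counting was not stated, so the counts of genes with a partner on the opposite strand are uncertain. Genes were named by the symbols in the files, which gave a symbol to 60295 of 60668 gene identifiers. The reference annotation gave a position to 58561 of them.

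Total counts were 259.9 to 356.8 M per library in the 200 nM experiment, 75 to 112.8 M in the 50 nM and siRNA experiments and 75.3 to 109.6 M in the PDX. The tests use the spread between libraries, so no counting interval is given for counts.

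Changes in gene level were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed with filterByExpr, library sizes were scaled by TMM, and all groups of a table entered 1 quasi-likelihood fit without a term for the replicate number. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05, and log2 changes are treated minus control. Levels are given as CPM, counts scaled to the library size. The SE of a log2 change was derived from the quasi-likelihood F statistic. Differences between 2 effects (between cell lines, between doses, and between the 200 nM oligonucleotide and siRNA) were tested in the same way as an interaction, 7 in all. Differences between doses and between oligonucleotide and siRNA set libraries of separate experiments side by side, so experiment and treatment cannot be told apart in them.

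Splicing was tested with limma 3.58.1 (trend) on the PSI of the 2 groups compared, for events with a value in every library and a range of at least 0.05. An event was called when its adjusted p was below 0.05 and its mean PSI differed by at least 0.10. The TRA2B poison exon, an alternative exon whose inclusion ends the reading frame early, was located by its coordinates between coding exons 1 and 2, and was also tested with an exact two-sided permutation test on its PSI. With 3 against 3 libraries that test cannot give a p below 0.1, and with 5 against 5 not below 0.00794.

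Before the data were examined, 28 gene lists (pathways, complexes and cell type markers) were written from general knowledge. Each was tested against all other genes with camera (limma) at its preset correlation of 0.01, and again with a correlation estimated from the residuals. Of these, 1 list and some genes are not reported by name, though they enter the counts of calls. List counts are given over all genes tested and adjusted over the list alone. Overlaps of called genes between comparisons were tested with Fisher's exact test, separately for rising and falling genes, over the genes tested in both.

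The genes named follow a rule written before the data were examined. It takes TRA2B and TRA2A, the 8 rising and 8 falling genes with the largest log2 change among called genes with a mean log2 CPM of at least 3 and no overlap between the groups' values, up to 4 members of each list with the smallest p, the 8 genes in each direction with the largest change in both cell lines, and the 5 genes with the smallest p for each difference between effects. After the values were seen, genes that overlap another gene on their strand with over 2% of their counts were left out, except where marked. Named splicing events were the poison exon, called events of SR protein genes, TRA2A and 6 genes taken as TRA2B targets from general knowledge, and the 5 events in each direction with the largest change per comparison and in both lines. Not every gene or event the rule allows is named.

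The alternatives planned for genes were DESeq2 1.42.0, RLE size factors, no low-count filter, a fit of the 2 compared groups alone, a term for the replicate number (a block) and each library left out in turn. For splicing they were PSI on the logit scale (bounded at 0.01), events with at least 2 values per group, no range filter, the block and each library left out in turn. List tests were repeated with an estimated correlation and with the block, and overlaps at an adjusted p of 0.01. Chosen after seeing the data were thinning of the 200 nM counts to the depth of the 50 nM experiment, a minimum mean CPM of 10 for the genes of splicing events, 1 fit of the siRNA splicing effect over both lines, removal of mitochondrial genes or of libraries with over 50% mitochondrial counts in the PDX, and PDX list tests with each library left out. Replicate numbers were taken to pair the samples in U87MG, where every same-number pair correlated above 0.1 in its deviations from the group means. They were not taken to pair those of MDA-MB-231 or the PDX. The U87MG correlations were 0.121 to 0.338. Treated replicate 2 at 50 nM and treated replicate 3 with siRNA correlated better with a control of another number. Blocked values stand beside U87MG results where they end a call or move a count by over 1.5 times.

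The edgeR and limma steps were tested on simulated data made from these libraries. Over the 7 comparisons, limma called 0% to 4.5% of events with a simulated PSI change of 0.2 and 47% to 78.8% of those with a change of 0.4. Splicing changes below 0.2 would therefore mostly be missed where few events change. Positions and tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.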

Results

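TRA2B is a splicing regulator of the SR protein family, and its own transcript carries a poison exon, an alternative exon that ends the reading frame early when it is included. The series measured what ASO-1570, an antisense oligonucleotide directed at TRA2B splicing, changed in gene levels and in splicing against a control oligonucleotide. It was given at 200 nM and at 50 nM to MDA-MB-231, a breast cancer cell line, and to U87MG, a glioblastoma cell line. An siRNA against TRA2B at 10 nM was set against a control siRNA in both lines, with 3 libraries in each of these 12 groups. A breast cancer PDX received ASO-1570 or the control oligonucleotide, with 5 tumours per group.

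Libraries of the 200 nM experiment held 259.9 to 356.8 M counts, those of the 50 nM and siRNA experiments 75 to 112.8 M, and those of the PDX 75.3 to 109.6 M. Mitochondrial genes took 1.73% to 3.16% of the counts of the cell line libraries. In the PDX they took 17.65% to 75.31%, with a mean of 52.9% ± 21.7 in treated and 33.2% ± 13.7 in control tumours (SD, n = 5 per group, exact two-sided permutation p = 0.111).

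Every library with ASO-1570 included the TRA2B poison exon more than its controls in both lines, a difference that passed the test in U87MG, and TRA2B mRNA fell in both lines at both doses. The siRNA lowered TRA2B mRNA further, with no detectable change in the exon. TRA2A, the closest paralog of TRA2B, rose in all 6 cell line comparisons. TRA2B (ENSG00000136527.18) lies on chromosome 3 from 185915906 to 185938136 (GRCh38, minus strand). Its poison exon spans 276 bases from 185931577 to 185931852, between coding exons 1 and 2, and the annotation places it only in transcripts classed as targets of nonsense-mediated decay, processed transcripts or retained introns. In U87MG its PSI rose from 0.098 ± 0.006 to 0.489 ± 0.068 at 200 nM (SD, n = 3 per group, limma adjusted p = 0.00185) and from 0.157 ± 0.01 to 0.536 ± 0.07 at 50 nM (limma adjusted p = 0.00416). In MDA-MB-231 it was 0.16 ± 0.001 in control and 0.42 ± 0.128 in treated libraries at 200 nM (limma adjusted p = 0.131), and 0.27 ± 0.031 and 0.482 ± 0.101 at 50 nM (limma adjusted p = 0.232), which did not pass the test across all events. All 3 treated libraries lay above all 3 controls in each of these 4 comparisons (exact p = 0.1, the smallest that 3 against 3 can give). With siRNA the PSI was 0.207 ± 0.025 in control and 0.246 ± 0.116 in treated MDA-MB-231 libraries (exact p = 0.9), and 0.112 ± 0.017 and 0.139 ± 0.032 in U87MG (exact p = 0.3).

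**Figure D1:**
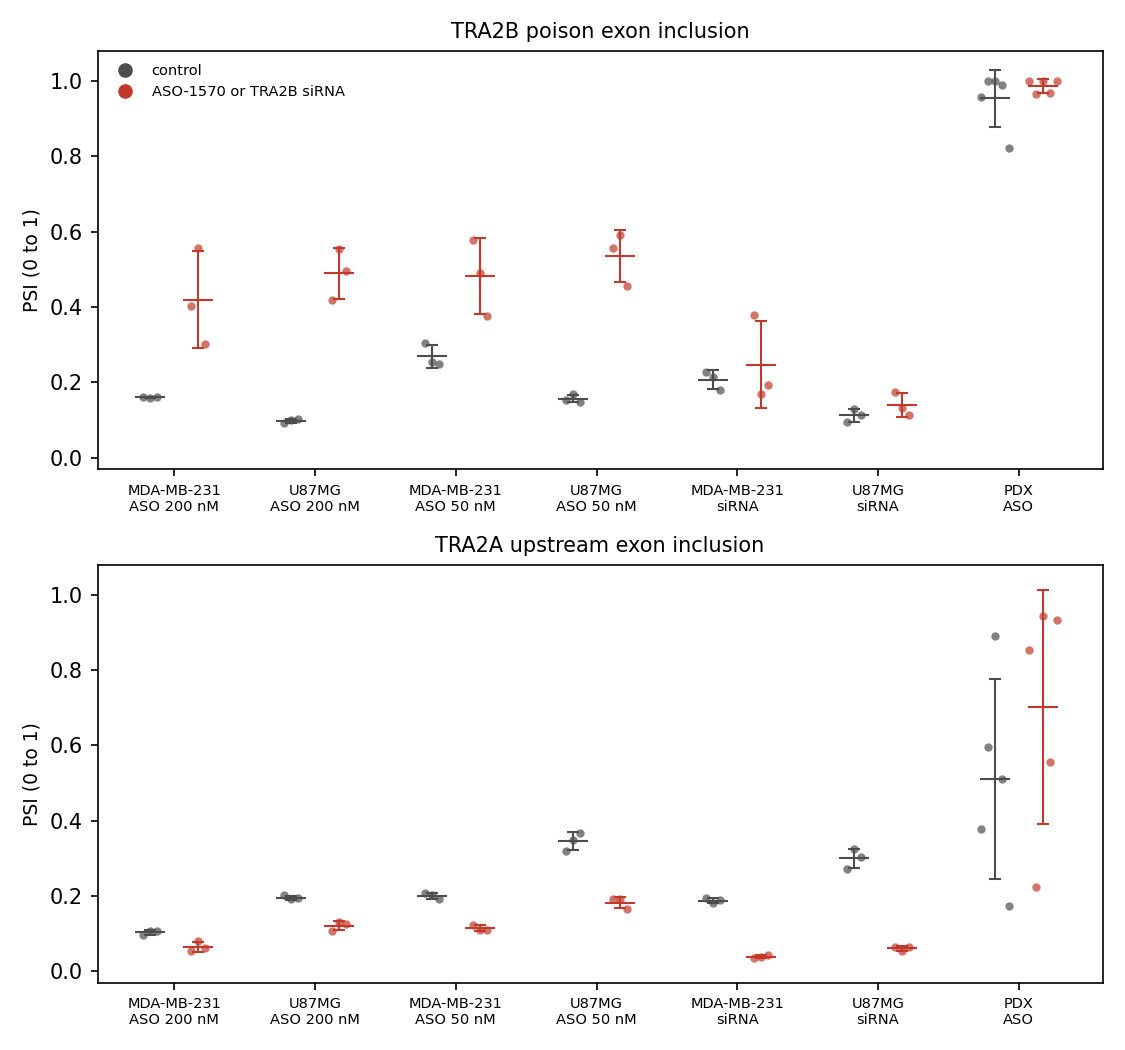
PSI (fraction, 0 to 1) of the TRA2B poison exon and of the 312-base TRA2A exon per library in control and treated groups of each comparison, with the mean and SD. In the 4 cell line comparisons of ASO-1570 all 3 treated libraries lie above all 3 controls for TRA2B, and in the 6 cell line comparisons all 3 lie below all 3 controls for TRA2A.

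TRA2B mRNA fell from 198 ± 7.24 to 109 ± 6.83 CPM in MDA-MB-231 at 200 nM (SD, n = 3 per group, log2 change -0.87, SE 0.061, edgeR adjusted p = 6.89e-06) and from 157 ± 5.32 to 76.7 ± 0.93 CPM in U87MG (-1.03, SE 0.061, adjusted p = 3.84e-07). At 50 nM it fell by 0.76 (SE 0.069, adjusted p = 3.23e-05) in MDA-MB-231 and by 1.12 (SE 0.07, adjusted p = 5.43e-07) in U87MG. With siRNA it fell from 192 ± 5.48 to 22.2 ± 0.733 CPM in MDA-MB-231 (8.66-fold, adjusted p = 8.55e-10) and from 181 ± 6.17 to 25.5 ± 3.05 CPM in U87MG (7.11-fold, adjusted p = 2.3e-09). TRA2A (ENSG00000164548.11), on chromosome 7 from 23504780 to 23532041, rose by 0.65 (SE 0.059, adjusted p = 3.34e-05) in MDA-MB-231 and 1.45 (SE 0.06, adjusted p = 7.44e-08) in U87MG at 200 nM. At 50 nM it rose by 0.65 (SE 0.05, adjusted p = 1.16e-05) and 1.34 (SE 0.051, adjusted p = 6.47e-08), and with siRNA by 1.05 (SE 0.042, adjusted p = 2.1e-07) and 1.55 (SE 0.043, adjusted p = 3.08e-09). An exon of 312 bases of TRA2A, from 23522121 to 23522432 between coding exons 1 and 2, had a PSI of 0.346 ± 0.024 in control and 0.183 ± 0.015 in treated U87MG libraries at 50 nM (limma adjusted p = 0.00769), a call that ended with a block for the replicate number (adjusted p = 0.0562, with a range of 0.0046 to 0.0562 over all alternatives). In the other oligonucleotide comparisons of the lines it was lower in treated libraries but not called, at 0.196 ± 0.005 and 0.122 ± 0.012 in U87MG at 200 nM (adjusted p = 0.0144, a change under 0.10), 0.104 ± 0.007 and 0.066 ± 0.013 in MDA-MB-231 at 200 nM (adjusted p = 0.354) and 0.201 ± 0.008 and 0.115 ± 0.008 in MDA-MB-231 at 50 nM (adjusted p = 0.164). In the siRNA experiment its PSI was 0.188 ± 0.006 in control and 0.039 ± 0.004 in treated MDA-MB-231 libraries (limma adjusted p = 0.257), and 0.3 ± 0.026 and 0.061 ± 0.006 in U87MG (adjusted p = 0.162), all 3 treated libraries lying below all 3 controls in each line (exact p = 0.1). This exon was looked at in the siRNA experiment after its values were seen.

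**Figure D2:**
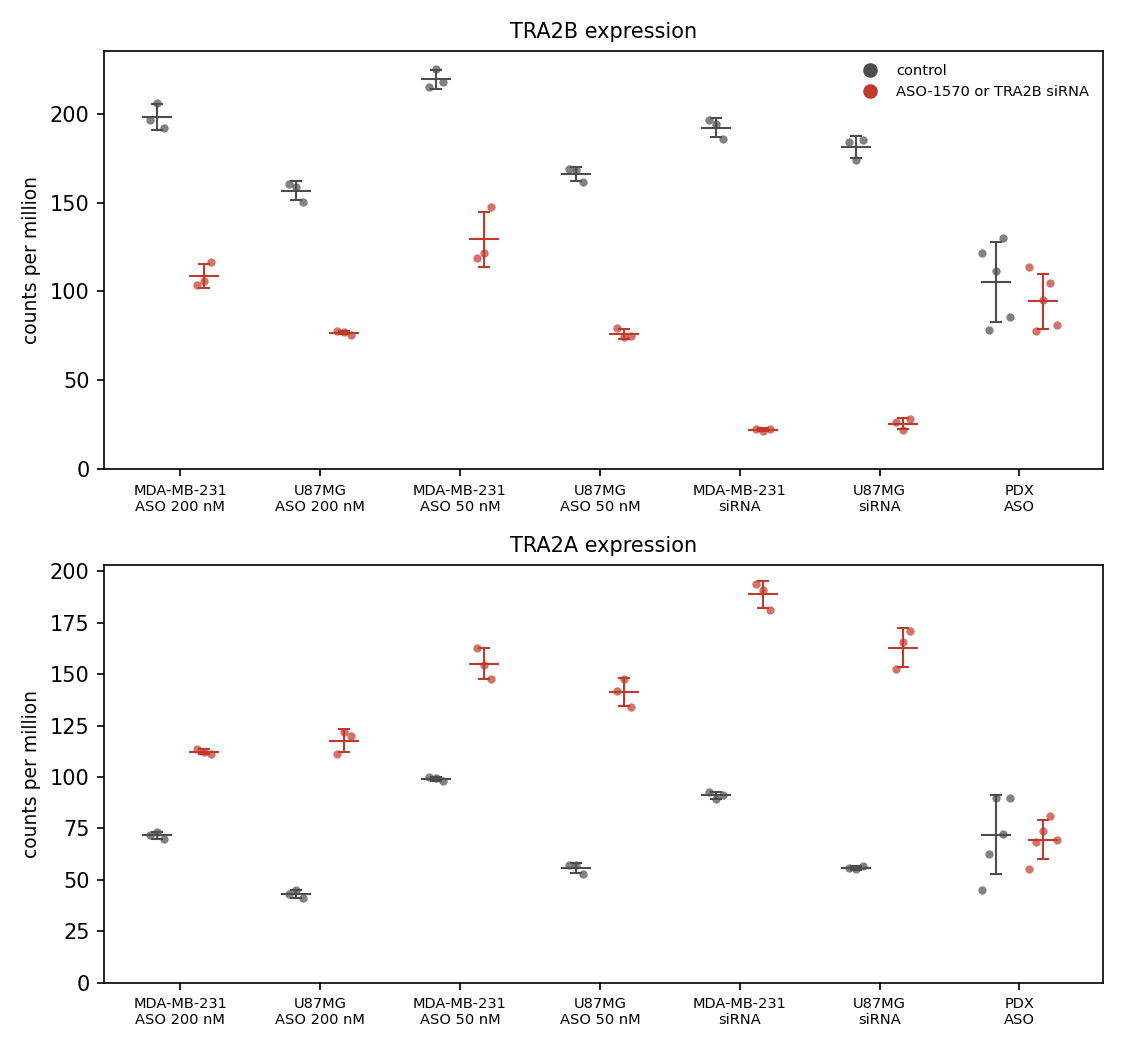
TRA2B and TRA2A level (CPM) per library in control and treated groups of each comparison, with the mean and SD. TRA2B is lower and TRA2A higher in the treated libraries of the 6 cell line comparisons, with TRA2B means of 22.2 and 25.5 CPM after siRNA.

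With 200 nM ASO-1570 in MDA-MB-231, 39 of 41 mitosis, 26 of 38 S phase, 15 of 23 DNA repair and 11 of 18 endoplasmic reticulum chaperone genes fell, and 17 of 23 NF-kB and cytokine genes rose. None of the 13 list calls held with an estimated correlation (smallest adjusted p = 0.41). IL11, a cytokine, fell from 29.9 ± 0.713 to 6.35 ± 0.955 CPM (SD, n = 3 per group, 4.7-fold), and NORAD, a long noncoding RNA that binds Pumilio proteins, fell from 502 ± 44.8 to 116 ± 25.1 CPM (4.34-fold). SLCO4A1, an organic anion transporter, fell from 21.1 to 4.86 CPM, AIDA from 143 to 44.3 CPM, and GLG1, a Golgi glycoprotein, from 193 to 60.2 CPM. LUM, a collagen-binding proteoglycan, rose from 1.32 ± 0.0876 to 13.5 ± 0.695 CPM (10.2-fold). IL6, an inflammatory cytokine, rose from 20.3 ± 3.24 to 61.3 ± 34.7 CPM (3.02-fold), ELF3, an epithelial transcription factor, rose 2.92-fold, and OXTR, the oxytocin receptor, rose 2.88-fold. Adjusted p for these genes was at most 0.00598 (edgeR). In all, 3049 genes rose and 3552 fell among 26159 tested, 1666 of them by at least 2-fold. Without control replicate 2 the count of changed genes was 4221 in place of 6601.

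Of the 41 mitosis genes, 39 fell in MDA-MB-231 at 200 nM (40 adjusted over the list alone), with a median log2 change of -0.61 (camera adjusted p = 4.56e-23, and adjusted p = 0.41 with an estimated correlation). Among them PLK1, a mitotic kinase, fell by 0.61 (SE 0.083), TPX2, a spindle assembly factor, by 0.61 (SE 0.085), and DLGAP5 by 1.20 (SE 0.164). FOXM1, a transcription factor of dividing cells, fell by 0.50 (SE 0.062). Of 38 S phase genes, 26 fell (27 fell and 1 rose adjusted over the list alone). The median change was -0.29 (camera adjusted p = 3.02e-10, and adjusted p = 0.41 with an estimated correlation). TYMS, thymidylate synthase, fell from 282 to 111 CPM and RRM2, a subunit of ribonucleotide reductase, from 290 to 143 CPM. Of 23 DNA repair genes, 15 fell (18 adjusted over the list alone), among them FANCI, a Fanconi anaemia protein, by 1.20 (SE 0.093) and XRCC2 by 1.03 (SE 0.09). Members had a median of -0.42 (camera adjusted p = 1e-09, and adjusted p = 0.41 with an estimated correlation). Of 18 endoplasmic reticulum chaperones, 11 fell (15 adjusted over the list alone). The list had a median of -0.50 (camera adjusted p = 1e-09, and adjusted p = 0.41 with an estimated correlation). EDEM1, which takes part in the disposal of misfolded glycoproteins, fell from 167 to 56.8 CPM, CANX, the lectin chaperone calnexin, from 1630 to 869 CPM, and HSPA5, the main chaperone of the compartment, from 2030 to 1300 CPM. Adjusted p for the genes named was at most 0.000778 (edgeR).

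Of 23 genes of the NF-kB and inflammatory cytokine list, 17 rose and 2 fell in MDA-MB-231 at 200 nM (18 and 2 adjusted over the list alone). The median over the list was 1.15 (camera adjusted p = 1.1e-07, and adjusted p = 0.55 with an estimated correlation). NFKBIA, the inhibitor of NF-kB and itself a target, rose from 44.9 to 112 CPM and RELB, an NF-kB subunit, from 22.4 to 56.2 CPM, while LIF, a cytokine, fell by 0.78 (SE 0.082). Of 27 hypoxia and glycolysis genes, 15 fell and 1 rose (17 and 1 adjusted over the list alone). Its members had a median of -0.39 (camera adjusted p = 2.34e-06, and adjusted p = 0.55 with an estimated correlation). VEGFA, an angiogenic factor, fell from 299 to 169 CPM and P4HA1, a collagen prolyl hydroxylase, from 229 to 105 CPM, while ADM, adrenomedullin, rose from 26.2 to 55.9 CPM. Of 34 extracellular matrix genes, 14 fell and 4 rose, the same counts adjusted over the list alone, with ITGB1, an integrin subunit, falling from 1580 to 549 CPM. The median log2 change was -0.22 (camera adjusted p = 0.000432, and adjusted p = 0.594 with an estimated correlation). Of 39 oxidative phosphorylation genes, 14 rose and 1 fell (21 and 1 adjusted over the list alone). Across members the median was 0.28 (camera adjusted p = 0.000525, and adjusted p = 0.73 with an estimated correlation). Of 15 snoRNA host genes, 8 rose and 1 fell (10 and 2 adjusted over the list alone). Its median change was 0.43 (camera adjusted p = 0.00529, and adjusted p = 0.73 with an estimated correlation). Other calls lay closer to the threshold. Of 24 sterol synthesis genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone). The median change was -0.23 (camera adjusted p = 0.0181, and adjusted p = 0.73 with an estimated correlation). Of 25 genes of the integrated stress response, 10 fell and 2 rose (10 and 4 adjusted over the list alone). Members had a median of -0.30 (camera adjusted p = 0.031, and adjusted p = 0.73 with an estimated correlation). Cytosolic ribosomal proteins, with 0 of 48 called, also over the list alone, had a median of 0.16 (camera adjusted p = 0.0312, and adjusted p = 0.859 with an estimated correlation). Fibroblast markers, of which 3 of 13 rose and 2 fell (4 and 2 adjusted over the list alone), had a median of 0.04 and a mean of 0.94 (camera adjusted p = 0.02, and adjusted p = 0.55 with an estimated correlation). Adjusted p for the genes named was at most 0.000385 (edgeR).

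In U87MG at 200 nM, 41 of 41 mitosis, 35 of 38 S phase, 13 of 23 NF-kB and cytokine and 22 of 34 matrix genes fell, and 12 of 15 heat shock genes and the cell cycle inhibitor CDKN1A rose. None of the 8 list calls held with an estimated correlation (smallest adjusted p = 0.146). GDF15, a stress-induced cytokine, rose from 61.1 ± 5.92 to 1200 ± 261 CPM (SD, n = 3 per group, 19.6-fold), and CDKN1A from 232 ± 4.59 to 855 ± 97.9 CPM (3.69-fold). MIR222HG, a microRNA host gene whose span holds its microRNAs and another noncoding gene, rose 17.4-fold. CCL20, a chemokine, fell 7.71-fold, UNC5B, a netrin receptor, fell 5.97-fold, and CXCL5, a chemokine, fell from 61.1 to 13.4 CPM. RRBP1, a ribosome-binding protein of the endoplasmic reticulum, fell from 162 to 36.4 CPM and GLG1 from 271 to 67.2 CPM. Adjusted p for these genes was at most 0.000212 (edgeR). In all, 6746 genes rose and 6257 fell among 26159 tested, 5460 of them by at least 2-fold.

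All 41 mitosis genes fell in U87MG at 200 nM, also adjusted over the list alone, with a median of -1.09 (camera adjusted p = 1.61e-28, and adjusted p = 0.228 with an estimated correlation). Among them KIF2C, a kinesin, fell by 1.19 (SE 0.078), PLK1 by 1.09 (SE 0.084) and CDC20, which activates the anaphase-promoting complex, by 1.02 (SE 0.079). Of 38 S phase genes, 35 fell, also adjusted over the list alone, with TYMS at 149 CPM in control and 45 CPM in treated libraries. The list had a median of -0.89 (camera adjusted p = 2.28e-20, and adjusted p = 0.146 with an estimated correlation). Of 23 repair genes, 18 fell and 2 rose (19 and 2 adjusted over the list alone), among them FANCI by 1.47 (SE 0.094). The median over the list was -0.52 (camera adjusted p = 2.56e-06, and adjusted p = 0.541 with an estimated correlation). BTG2, an antiproliferative protein, rose by 2.07 (SE 0.165) and CCNG1, cyclin G, from 124 to 339 CPM. Adjusted p for the genes named was at most 1.9e-06 (edgeR).

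Of 15 heat shock genes, 12 rose and 3 fell in U87MG at 200 nM, also adjusted over the list alone, with BAG3, a co-chaperone, at 99.5 CPM in control and 216 CPM in treated libraries. The median log2 change was 0.70 (camera adjusted p = 0.00029, and adjusted p = 0.541 with an estimated correlation). Of 23 NF-kB and cytokine genes, 13 fell and 3 rose, also adjusted over the list alone. Across members the median was -0.49 (camera adjusted p = 0.0134, and adjusted p = 0.85 with an estimated correlation). IL1B, a central inflammatory cytokine, fell from 4410 to 1650 CPM and CSF2, a myeloid growth factor, from 18 to 3.48 CPM. Of 34 matrix genes, 22 fell and 4 rose (23 and 5 adjusted over the list alone), with ITGB1 falling from 1730 to 602 CPM. Its median change was -0.53 (camera adjusted p = 0.00343, and adjusted p = 0.818 with an estimated correlation). CCN1 and CCN2, matrix-associated growth factors, rose by 1.28 (SE 0.1) and 1.12 (SE 0.105). Of 15 snoRNA host genes, 10 rose and 3 fell, also adjusted over the list alone, with SNHG1 at 86.9 CPM in control and 217 CPM in treated libraries. The median change was 0.61 (camera adjusted p = 0.0082, and adjusted p = 0.85 with an estimated correlation). Adjusted p for the genes named was at most 7.51e-05 (edgeR). Endoplasmic reticulum chaperones and sterol synthesis genes were called only with a block for the replicate number (camera adjusted p = 0.0386 and 0.014, against 0.0588 and 0.123 without it, and 0.834 and 0.866 with an estimated correlation).

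The lines shared many changes at 200 nM and differed in others. Genes rising in both lines numbered 1916 against 786.3 expected (Fisher odds ratio 6.4) and genes falling in both 2442 against 849.6 expected (10.8), and 90.9% of the 4792 genes called in both had the same direction. The effects differed between the lines for 6183 of 26159 genes (3008 higher and 3175 lower in MDA-MB-231). GDF15 changed by -0.36 in MDA-MB-231 and 4.29 in U87MG (adjusted p of the difference 8.65e-07) and CDKN1A by -0.27 and 1.88 (adjusted p = 1.28e-05). The NF-kB and cytokine list was higher in MDA-MB-231 than in U87MG by a median of 1.59 (camera adjusted p = 1.59e-13, and adjusted p = 0.323 with an estimated correlation). Of 14 SR protein genes, 2 rose and 2 fell in MDA-MB-231 (median -0.06, mean 0, camera adjusted p = 0.678) and 6 rose and 2 fell in U87MG (median 0.02, camera adjusted p = 0.541), also adjusted over the list alone, and neither list was called. TRA2A rose less in MDA-MB-231 than in U87MG, with a difference of -0.80 (adjusted p = 0.000134), and the change in TRA2B differed by 0.16 (adjusted p = 0.199).

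With 50 nM ASO-1570 in MDA-MB-231, 41 of 41 mitosis, 29 of 38 S phase and 16 of 18 endoplasmic reticulum chaperone genes fell, and 12 of 36 interferon response genes rose. None of the 12 list calls held with an estimated correlation (smallest adjusted p = 0.153). IL11 fell from 24.7 to 5.25 CPM (n = 3 per group, 4.7-fold) and NORAD from 742 to 231 CPM (3.21-fold). TYMS fell from 281 ± 5.61 to 91.3 ± 32.7 CPM (SD) and EPDR1 from 55.1 to 21.4 CPM. LUM rose from 1.9 to 16.9 CPM (8.87-fold), OXTR from 9.62 to 30.9 CPM, PPARGC1A, a coactivator of mitochondrial genes, from 5.92 to 17.1 CPM, and VGLL3 from 13.2 to 33.7 CPM. Adjusted p for these genes was at most 0.000781 (edgeR). Of 23989 genes tested, 2431 rose and 3159 fell, 903 of them by at least 2-fold. Without treated replicate 2 the count of changed genes was 3696 in place of 5590.

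All 41 mitosis genes fell in MDA-MB-231 at 50 nM, also adjusted over the list alone, among them AURKB, a mitotic kinase, by 0.75 (SE 0.096) and FOXM1 by 0.39 (SE 0.041). Members had a median of -0.50 (camera adjusted p = 4.42e-23, and adjusted p = 0.499 with an estimated correlation). Of 18 endoplasmic reticulum chaperones, 16 fell (17 adjusted over the list alone), with EDEM1 falling from 223 to 91.9 CPM and HSPA5 from 2060 to 1260 CPM. The list had a median of -0.50 (camera adjusted p = 1.07e-18, and adjusted p = 0.153 with an estimated correlation). Of 38 S phase genes, 29 fell (31 adjusted over the list alone). The median over the list was -0.36 (camera adjusted p = 7.86e-17, and adjusted p = 0.425 with an estimated correlation). Of 23 repair genes, 12 fell (13 adjusted over the list alone). Its members had a median of -0.24 (camera adjusted p = 2.76e-07, and adjusted p = 0.425 with an estimated correlation). Of 27 hypoxia and glycolysis genes, 13 fell and 1 rose (18 and 1 adjusted over the list alone). The median log2 change was -0.35 (camera adjusted p = 2.35e-07, and adjusted p = 0.612 with an estimated correlation). Of 23 NF-kB and cytokine genes, 7 rose and 2 fell (13 and 2 adjusted over the list alone), with NFKBIA rising by 0.94 (SE 0.184). Across members the median was 0.80 (camera adjusted p = 0.00188, and adjusted p = 0.76 with an estimated correlation). Of 36 interferon response genes, 12 rose and 2 fell (13 and 2 adjusted over the list alone), among them IFIH1, an RNA sensor, by 0.62 (SE 0.104), IFIT2 by 0.64 (SE 0.054) and STAT2 by 0.39 (SE 0.062). Its median change was 0.19 (camera adjusted p = 0.00734, and adjusted p = 0.669 with an estimated correlation). Another 5 lists were called. Sterol synthesis had a median of -0.16 (camera adjusted p = 0.00118, and adjusted p = 0.76 with an estimated correlation). Matrix genes had a median of -0.15 (adjusted p = 0.002, and adjusted p = 0.669 with an estimated correlation). The integrated stress response had a median of -0.23 (adjusted p = 0.00784, and adjusted p = 0.612 with an estimated correlation). Ribosomal proteins had a median of -0.06 (adjusted p = 0.00784, and adjusted p = 0.788 with an estimated correlation). Fibroblast markers had a median of 0.22 (adjusted p = 0.0213, and adjusted p = 0.552 with an estimated correlation). Heat shock proteins were not called (camera adjusted p = 0.0672), with a median of -0.15 and a mean of 0.21. Adjusted p for the genes named was at most 0.00354 (edgeR).

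With 50 nM ASO-1570 in U87MG, GDF15 and CDKN1A rose, and 41 of 41 mitosis and 36 of 38 S phase genes fell. None of the 10 list calls held with an estimated correlation (smallest adjusted p = 0.186). GDF15 rose from 14.8 ± 1.8 to 340 ± 166 CPM (SD, n = 3 per group, 23-fold), CDKN1A from 112 to 414 CPM, MIR222HG from 6.62 to 104 CPM, and SLC3A2, a subunit of amino acid transporters, by 2.05 (SE 0.212). CCL20 fell from 22.7 to 3.81 CPM, CXCL5 from 77 to 17.4 CPM, GLG1 from 301 to 72.9 CPM and NORAD from 771 to 188 CPM. Adjusted p for these genes was at most 6.88e-05 (edgeR). Of 23989 genes tested, 6699 rose and 6399 fell, 4159 of them by at least 2-fold. All 41 mitosis genes fell, also adjusted over the list alone, among them KIF23, a kinesin of cytokinesis, by 1.62 (SE 0.122) and ANLN, anillin, by 1.29 (SE 0.082). The median change was -1.09 (camera adjusted p = 5.26e-35, and adjusted p = 0.23 with an estimated correlation). Of 38 S phase genes, 36 fell, also adjusted over the list alone. Members had a median of -0.83 (camera adjusted p = 6.09e-24, and adjusted p = 0.193 with an estimated correlation). Of 23 repair genes, 19 fell and 2 rose (20 and 2 adjusted over the list alone), with FANCD2, a Fanconi anaemia protein, falling by 1.36 (SE 0.105). The list had a median of -0.57 (camera adjusted p = 4.41e-09, and adjusted p = 0.193 with an estimated correlation). PHLDA3 rose by 1.16 (SE 0.076). Further calls had larger p. Matrix genes had a median of -0.45 (camera adjusted p = 0.00376, and adjusted p = 0.933 with an estimated correlation), and snoRNA hosts of 0.51 (adjusted p = 0.00431, and adjusted p = 0.933 with an estimated correlation). Sterol synthesis genes had a median of -0.29 (adjusted p = 0.0166, and adjusted p = 0.951 with an estimated correlation). Endoplasmic reticulum chaperones were at -0.25 (adjusted p = 0.0258, and adjusted p = 0.933 with an estimated correlation). Heat shock proteins were at 0.63 (adjusted p = 0.029, and adjusted p = 0.951 with an estimated correlation), and NF-kB and cytokine genes at -0.42 (adjusted p = 0.0395, and adjusted p = 0.951 with an estimated correlation). Adjusted p for the list members named was at most 1.63e-06 (edgeR).

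**Figure D3:**
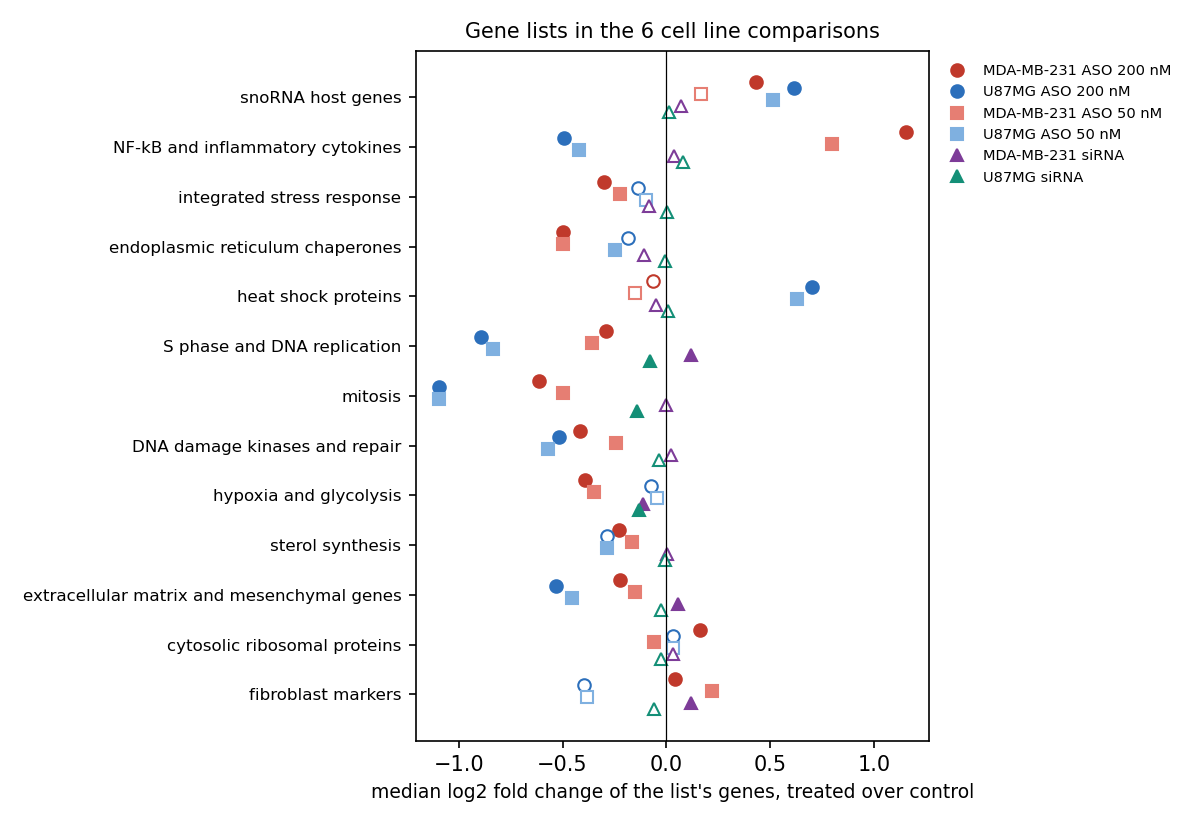
Median log2 change (treated minus control) of the genes of selected lists in the 6 cell line comparisons, with filled symbols where camera called the list at its preset correlation and open symbols where it did not. The mitosis list has medians of -0.61 and -1.09 in MDA-MB-231 and U87MG at 200 nM.

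Within each line, most genes called at both doses changed in the same direction. Of genes called at both doses, 99.8% of 3817 in MDA-MB-231 and 99.4% of 9830 in U87MG had the same direction, and overlaps were 1378 rising (298.8 expected) and 2432 falling (488.9 expected) in MDA-MB-231, and 4803 (1648.3 expected) and 4967 (1716.1 expected) in U87MG. The change in TRA2B differed between doses by -0.07 in MDA-MB-231 (SE 0.116, adjusted p = 0.879) and by 0.06 in U87MG (SE 0.057, adjusted p = 0.723), and that in TRA2A by 0.04 (adjusted p = 0.894) and 0.08 (adjusted p = 0.73). Among the lists in MDA-MB-231, camera called 5 as higher at 200 nM than at 50 nM, by medians of 0.26 for ribosomal proteins (adjusted p = 4.42e-12), 0.25 for oxidative phosphorylation (1.43e-08), 0.29 for snoRNA hosts (8.72e-05), 0.41 for NF-kB and cytokine genes (0.013) and 0.12 for heat shock proteins (0.0263). It called repair genes as lower, by -0.14 (0.00756), and all 6 calls were lost with an estimated correlation (adjusted p = 0.947 for each). In U87MG it called replication-dependent histones, by 0.34 (adjusted p = 0.00552), which was lost too (adjusted p = 0.902). In MDA-MB-231 the effect differed for 1 of 24002 genes (1088 at an unadjusted p under 0.05, and 56 by DESeq2), BNIP3P17, a pseudogene whose counts are uncertain. It had 27 to 55 counts in control and 0 in each treated library at 200 nM, and 102 to 165 and 73 to 87 at 50 nM. In U87MG it differed for 309 of 26015 genes (110 with a block for the replicate number, 163 without the low-count filter and 893 by DESeq2). Among the genes with the smallest p in U87MG, STBD1 is uncertain because it overlaps a read-through gene. ZNF48 differed by -2.27 (adjusted p = 2.02e-05) and is uncertain too, with 2709 to 3355 counts in control libraries at 200 nM and 97 to 107 at 50 nM. MYH10, whose counts are uncertain as well, differed by -2.67 (adjusted p = 0.000128), with 101 to 124 counts in treated libraries at 200 nM and 629 to 831 at 50 nM. Leaving out 1 library took the U87MG count to 165 (treated 200 nM replicate 3), 192 (treated 200 nM replicate 2), 179 and 151 (control 200 nM replicates 1 and 3), 129 (treated 50 nM replicate 1), and 149, 105 and 122 (control 50 nM replicates 1, 2 and 3). In MDA-MB-231 the count was then 0 to 10. Because doses were run in separate experiments at different depths, dose and experiment cannot be told apart.

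At 50 nM the lines also shared changes, with 1429 genes rising in both (678.9 expected, odds ratio 4.41) and 2276 falling in both (842.7 expected, 10.4), and 89.8% of 4124 genes called in both had the same direction. The effects differed between the lines for 6760 of 23989 genes. MARVELD2, a tight junction protein, changed by 0.32 in MDA-MB-231 and by 5.24 in U87MG, where control libraries held 6 to 7 counts (adjusted p = 5.77e-06), and SLC20A1, a phosphate transporter, by -0.22 and 0.82. TRA2B fell more in U87MG, with a difference of 0.36 (adjusted p = 0.0176), and TRA2A rose more there, with a difference of -0.70 (adjusted p = 0.000141).

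The siRNA against TRA2B changed fewer genes, and most of those by small amounts. In MDA-MB-231, NGLY1, which removes glycans from misfolded proteins, fell from 44.6 to 24.8 CPM (n = 3 per group, log2 change -0.85, SE 0.045), and SLC36A1, an amino acid transporter, rose from 11.3 to 26 CPM. LOX, which crosslinks collagen, rose from 152 to 297 CPM, NPR3, a natriuretic peptide receptor, by 0.99 (SE 0.074), and SRRM1, a splicing coactivator, from 154 to 201 CPM. IL11 fell by 0.76 (SE 0.102), MTM1, a lipid phosphatase, by 0.70 (SE 0.061) and the SR protein SRSF4 by 0.22 (SE 0.042). Adjusted p for these genes was at most 0.0103 (edgeR). Of 23141 genes tested, 844 rose and 832 fell, 95 of them by at least 2-fold. Of 38 S phase genes, 8 rose (22 rose and 1 fell adjusted over the list alone), with RRM1, a subunit of ribonucleotide reductase, rising by 0.22 (SE 0.033, adjusted p = 0.00195). Its members had a median of 0.12 (camera adjusted p = 2.8e-06, and adjusted p = 0.894 with an estimated correlation). Of 34 matrix genes, 7 rose and 1 fell (11 and 2 adjusted over the list alone), with COL6A3, a collagen chain, rising by 0.71 (SE 0.077, adjusted p = 0.000334). The median log2 change was 0.06 (camera adjusted p = 2.35e-05, and adjusted p = 0.511 with an estimated correlation). Of 27 hypoxia genes, 3 fell and 2 rose (7 and 2 adjusted over the list alone). Across members the median was -0.11 (camera adjusted p = 0.000388, and adjusted p = 0.894 with an estimated correlation). Fibroblast markers were called upward (1 rose, 4 rose and 1 fell adjusted over the list alone). Its median change was 0.12 (camera adjusted p = 0.0449, and adjusted p = 0.511 with an estimated correlation). DESeq2 changed the count of called genes from 1676 to 2638 and no low-count filter to 982. Without control replicate 1, control replicate 2, treated replicate 1 or treated replicate 2 it was 796, 1089, 974 or 946.

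In U87MG the siRNA lowered NGLY1 from 43.4 to 20.3 CPM (n = 3 per group, -1.10, SE 0.045), FOXO3, a transcription factor, by 0.67 (SE 0.05), RC3H2, an RNA-binding ubiquitin ligase, by 0.71 (SE 0.053), PGF, placental growth factor, by 0.67 (SE 0.091), COL5A1, a collagen chain, by 0.51 (SE 0.043) and SRSF4 by 0.38 (SE 0.042). RSPO3, an enhancer of Wnt signalling, rose by 0.87 (SE 0.138), AUH by 0.62 (SE 0.062) and SRRM1 by 0.25 (SE 0.031). Adjusted p for these genes was at most 0.00515 (edgeR). Of 23141 genes tested, 370 rose and 601 fell, 50 of them by at least 2-fold. Of 41 mitosis genes, 13 fell (25 adjusted over the list alone), among them PLK1 by 0.41 (SE 0.053, adjusted p = 0.00213) and KIF14 by 0.30 (SE 0.043, adjusted p = 0.00352). The median change was -0.14 (camera adjusted p = 5.49e-23, and adjusted p = 0.221 with an estimated correlation). Of 27 hypoxia genes, 4 fell (6 adjusted over the list alone). Members had a median of -0.13 (camera adjusted p = 2.17e-08, and adjusted p = 0.898 with an estimated correlation). Of 38 S phase genes, 7 fell and 1 rose (10 and 1 adjusted over the list alone), with EXO1, a repair exonuclease, falling by 0.45 (SE 0.046, adjusted p = 0.000404). The list had a median of -0.08 (camera adjusted p = 6.91e-07, and adjusted p = 0.898 with an estimated correlation). DESeq2 changed the count of called genes from 971 to 1849 and no low-count filter to 481. Without control replicate 1, 2 or 3 or treated replicate 1 it was 476, 613, 629 or 529.

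The siRNA changes overlapped between the lines. Of the genes called in both, 142 rose (13.5 expected, Fisher exact p = 1.23e-107) and 254 fell (21.6 expected, p = 2.51e-213), and 99% of 400 had the same direction. The effects differed for 122 of 23141 genes (2590 at an unadjusted p under 0.05). Among these were NPR3, at 0.99 in MDA-MB-231 and -0.12 in U87MG (adjusted p of the difference 0.00242), and SEPTIN4, a septin, at 0.84 and -0.53. TRA2A rose less in MDA-MB-231, with a difference of -0.50 (adjusted p = 0.00711), and TRA2B differed by -0.29 (adjusted p = 0.26), which passed the test without U87MG treated replicate 2 (-0.38, adjusted p = 0.0324) but not under any other alternative (adjusted p of at least 0.0794). The count of 122 was 509 by DESeq2, 80 with RLE size factors and 27 without the low-count filter. It was 31, 59 and 61 without MDA-MB-231 control replicates 1, 2 and 3, 48, 33 and 63 without treated replicates 1, 2 and 3, 53, 44 and 54 without U87MG control replicates 1, 2 and 3, and 26 without U87MG treated replicate 1.

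Set against the siRNA, 200 nM ASO-1570 changed many other genes while lowering TRA2B less. The TRA2B change differed by 2.28 (SE 0.079, adjusted p = 4.84e-08) in MDA-MB-231 and by 1.82 (SE 0.1, adjusted p = 2.13e-07) in U87MG. Effects differed for 3678 of 23898 genes in MDA-MB-231 (1638 higher and 2040 lower with the oligonucleotide) and for 11741 of 25781 in U87MG (5610 and 6131). In MDA-MB-231, LUM was higher by 3.16 (adjusted p = 6.96e-07) and FANCI lower by -1.36 (adjusted p = 1.42e-05), and CTDSPL, a phosphatase, lower by -1.77 (adjusted p = 6.79e-06). In U87MG, AIDA was lower by -1.64 (adjusted p = 4.75e-08), MRPS31, a mitochondrial ribosomal protein, by -1.79 (adjusted p = 5.01e-08), and PIKFYVE, a lipid kinase, higher by 1.60 (adjusted p = 5.01e-08). Mitosis genes were lower with the oligonucleotide than with siRNA, by a median difference of -0.56 in MDA-MB-231 (camera adjusted p = 3.09e-28, and adjusted p = 0.0262 with an estimated correlation), where their median with siRNA was 0. In U87MG the difference was -0.88 (camera adjusted p = 4.91e-23), a call that was lost with an estimated correlation (adjusted p = 0.409). Of genes called in both treatments of MDA-MB-231, 105 rose where 103.9 were expected (odds ratio 1.01, Fisher exact p = 0.915) and 316 fell where 134.1 were expected (3.4, p = 1.65e-54), and 59% of 713 had the same direction. In U87MG, 132 rose (88.1 expected, 1.8, Fisher exact p = 2.5e-07) and 341 fell (169.9 expected, 3.46, Fisher exact p = 2.02e-49), and 71.8% of 659 had the same direction. The MDA-MB-231 count of 3678 was 2415 without the low-count filter, 5629 without treated ASO replicate 3, 2446 without control ASO replicate 2, 2140, 2243 and 2279 without control siRNA replicates 1, 2 and 3, and 2258 and 2149 without treated siRNA replicates 1 and 2. Treatment and experiment cannot be told apart in these values.

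Splicing changed widely in U87MG with ASO-1570, mostly as skipping of cassette exons. At 200 nM, 4480 events rose and 11577 fell in PSI among 82102 tested (limma), in 5565 genes. Among 54239 cassette exon events 2427 rose and 9573 fell. An exon counts more than once where its neighbouring exons differ, and the 16057 called events covered 13462 distinct regions. An exon of CNN3, a calponin, on chromosome 1 from 94902121 to 94902258 rose from 0.207 ± 0.027 to 1 (SD, n = 3 per group, adjusted p = 0.000152), and an exon of FCF1, a ribosome biogenesis factor, on chromosome 14 from 74713485 to 74713620 rose from 0.059 ± 0.027 to 0.8 ± 0.128 (adjusted p = 0.00168). An exon of FAT1, a cadherin, on chromosome 4 from 186590368 to 186590403 fell from 1 to 0.081 ± 0.01 (adjusted p = 0.000105), and an exon of FAR1, an enzyme of ether lipid synthesis, on chromosome 11 from 13712966 to 13713033 fell from 1 to 0.093 ± 0.038 (adjusted p = 0.000124). In CD44, a cell adhesion receptor, an exon from 35204512 to 35204640 on chromosome 11 fell from 0.721 ± 0.033 to 0.333 ± 0.005 (adjusted p = 0.000787) and another from 35209965 to 35210054 rose from 0.141 ± 0.017 to 0.438 ± 0.016 (adjusted p = 0.000691). In SRSF2, an SR protein, an exon of 104 bases on chromosome 17 from 76735772 to 76735875 rose from 0.055 ± 0.003 to 0.182 ± 0.033 (adjusted p = 0.00827). In TRA2A, an exon of 301 bases from 23522132 to 23522432, counted against an upstream exon from 23531181 to 23531270, fell from 0.775 ± 0.037 to 0.4 ± 0.012 (adjusted p = 0.00115). At 50 nM in U87MG, 2568 events rose and 6661 fell among 67014 tested, with CNN3 at 0.269 ± 0.042 and 0.998 ± 0.001 (adjusted p = 0.000671), FCF1 at 0.109 ± 0.009 and 0.906 ± 0.064 (adjusted p = 0.000749) and FAT1 at 1 and 0.094 ± 0.027 (adjusted p = 0.000344). With a block for the replicate number, 10419 and 2885 events were called in place of 16057 and 9229. Without treated replicate 1 or control replicates 1, 2 and 3 at 50 nM, 6048, 3723, 3575 and 3639 were called.

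In MDA-MB-231 fewer events passed the test, at 275 rising and 717 falling of 69852 at 200 nM (671 genes) and 42 rising and 67 falling of 54829 at 50 nM (93 genes). The same exons of CNN3, FCF1 and FAT1 were among them at 200 nM. CNN3 rose from 0.242 ± 0.017 to 0.998 ± 0.001 (SD, n = 3 per group, limma adjusted p = 0.00101), FCF1 from 0.096 ± 0.058 to 0.944 ± 0.097 (adjusted p = 0.00709), and FAT1 fell from 1 to 0.032 ± 0.015 (adjusted p = 0.000279). NAP1L4, a histone chaperone, lost an exon on chromosome 11 from 2954301 to 2954410, from 1 to 0.017 ± 0.012 (adjusted p = 0.000279). At 50 nM, an exon of DCK, deoxycytidine kinase, on chromosome 4 from 71028623 to 71028719 fell from 1 to 0.073 (adjusted p = 0.000402), and an exon of RPS27L on chromosome 15 from 63156787 to 63156973 fell from 1 to 0.03 (adjusted p = 0.000402). Called in both lines at 200 nM were 205 rising (18.2 expected, Fisher exact p = 9.58e-182) and 569 falling events (108.2 expected), and 99.9% of 775 had the same direction. The count of 992 was 2362 on the logit scale, 400 without the range filter, 183, 155 and 2452 without treated replicates 1, 2 and 3, and 160, 145 and 144 without control replicates 1, 2 and 3. With a block for the replicate number, which does not pair these samples, it was 0 at both doses. The count of 109 was 452 on the logit scale, 41 without the range filter, 194 for genes with a mean CPM of at least 10 (chosen after seeing the data), 23, 46 and 499 without treated replicates 1, 2 and 3, and 31, 34 and 46 without control replicates 1, 2 and 3.

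With siRNA, limma called 0 of 62430 events in MDA-MB-231 (3676 at an unadjusted p under 0.05) and 0 of 63880 in U87MG (3417). On the logit scale it called 0 and 6, with at least 2 values per group 29 and 53, and without the range filter 4 and 1. A single fit of the mean siRNA effect over both lines, chosen after seeing the data, called 97 rising and 218 falling events among 52502 (5998 at an unadjusted p under 0.05). The 312-base exon of TRA2A was among those that fell (adjusted p = 7.19e-05). An exon of SGO1, which protects centromeric cohesion, on chromosome 3 from 20174249 to 20175055 fell from 0.861 to 0.536 in MDA-MB-231 and from 0.65 to 0.32 in U87MG (adjusted p = 8.21e-05). An exon of NGLY1 on chromosome 3 from 25736004 to 25736149 was at 0.833 and 0.536 in MDA-MB-231 and 0.888 and 0.733 in U87MG. Exons of the mitotic genes NUF2 (chromosome 1, 163345678 to 163345818, 0.962 to 0.773 and 0.981 to 0.81, adjusted p = 0.00048) and CENPE (chromosome 4, 103163479 to 103163553, 0.565 to 0.384 and 0.36 to 0.152, adjusted p = 0.00137) also fell. Left out in turn, single libraries gave 8, 7 and 11 (control replicates 1, 2 and 3) and 3, 3 and 3 (treated replicates 1, 2 and 3) called events in MDA-MB-231, and 9, 3 and 4 and 6, 10 and 12 in U87MG.

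In the PDX no gene and no splicing event passed the test. TRA2B stood at 105 ± 22.6 CPM in control and 94.5 ± 15.4 CPM in treated tumours (SD, n = 5 per group, log2 change -0.16, SE 0.202, edgeR adjusted p = 0.707), and TRA2A at 72 ± 19.1 and 69.6 ± 9.34 CPM (adjusted p = 0.921). The poison exon had a PSI of 0.955 ± 0.075 in control and 0.987 ± 0.018 in treated tumours (limma adjusted p = 0.763, exact permutation p = 0.484, smallest possible 0.00794). Values this near 1 leave little room for a rise. Cell line control means were 0.098 to 0.27 and event depth is unknown, so this PDX level is uncertain. Levels in control and treated tumours were 13 ± 25.3 and 0.955 ± 0.65 CPM for CCL20 and 50.3 ± 84.7 and 9.81 ± 2.97 CPM for TNFAIP3, a brake on NF-kB signalling. For CXCL1, a chemokine whose counts are uncertain because it shares sequence with its paralogs, they were 15 ± 23.8 and 2.63 ± 1.43 CPM. Control replicate 4 carries these control means, which without it were 1.69 ± 0.622 for CCL20, 12.5 ± 4.51 for TNFAIP3 and 4.35 ± 2.02 CPM for CXCL1. None of these passed the test (adjusted p = 0.487 for each). edgeR called 0 of 23812 genes (2053 at an unadjusted p under 0.05), DESeq2 called 0, and limma called 0 of 66867 events (2769 at an unadjusted p under 0.05), or 1 without treated replicate 1 and 7 with at least 2 values per group. In a test with simulated changes, edgeR recovered 3% of those of log2 1 and 57.6% of those of log2 2 in the PDX, against at least 85.1% of those of log2 1 in each cell line table, so moderate changes were not detectable in these tumours.

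Of the 28 lists, 11 were called downward in the PDX, with 0 member genes called, also adjusted over the list alone. The lowest medians were those of the NF-kB and cytokine list (-1.32, camera adjusted p = 1.79e-05), hypoxia and glycolysis (-0.54, adjusted p = 1.79e-05) and heat shock proteins (-0.49, adjusted p = 0.0192), each with adjusted p = 0.728 with an estimated correlation. The other 8 calls were oxidative phosphorylation (-0.41, adjusted p = 0.000642), hnRNPs (-0.41, adjusted p = 0.000749), apoptosis regulators (-0.46, adjusted p = 0.00348), mitosis (-0.26, adjusted p = 0.00779), ribosomal proteins (-0.22, adjusted p = 0.00796), endoplasmic reticulum chaperones (-0.42, adjusted p = 0.0134), the integrated stress response (-0.37, adjusted p = 0.0192) and sterol synthesis (-0.33, adjusted p = 0.0209), again each with adjusted p = 0.728 with an estimated correlation. Markers of other cell types were not called, at adjusted p = 0.52 for fibroblasts, 0.896 for endothelium, 0.635 for macrophages and neutrophils and 0.98 for lymphocytes. In a xenograft such cells would come from the mouse, and the median member of each of these 4 lists lay below 1 CPM, so this says nothing about the cell composition of the tumours. The fibroblast list had a median of -0.14 and a mean of 0.09, with the test upward, and the lymphocyte list a median of 0.54 with the test downward. Leaving out libraries over 50% mitochondrial counts, chosen after seeing the data, kept treated replicates 1 and 2 and control replicates 1 to 4. Among these tumours only the NF-kB and hypoxia lists were called (medians -1.17 and -0.48, each with adjusted p = 2.84e-08, and adjusted p = 0.89 with an estimated correlation). The NF-kB genes were highest in control replicate 4, at 58.3 CPM of CCL20 against 2.26 CPM in the next control, and without it the list had a median of -0.46 (adjusted p = 0.00654, and adjusted p = 0.803 with an estimated correlation). The count of 11 was 8 to 13 with 1 tumour left out, and 0 in each case with an estimated correlation.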

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

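Of the tests reported here, the splits of the samples and the test of exons that start near full inclusion were chosen before their results were seen, and the tests of depth, replicate spread, read number, TRA2B loss and the evenness and size of the response were chosen after.

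In the PDX, control replicate 4 stood apart from the other 4 controls in the levels of 3 genes. The gap between the highest control and the next, over the range of the 5 controls, was 0.976 for CCL20, 0.914 for CXCL1 and 0.957 for TNFAIP3. The lowest PSI of the TRA2B poison exon gave 0.768, but PSI and count columns of the PDX could not be matched, so whether it is the same tumour is unknown. The limit for 5 samples is 0.71. Of 22 groups of 5 values tested, 4 lay above it, and chance puts about 1 in 20 there. As 3 of the 4 come from 1 library and from genes of 1 list, they are not independent and their number cannot be set against that share. No explanation was tested for these values.

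The effect of 200 nM ASO-1570 differed between the lines for 6183 genes (test of the interaction, MDA-MB-231 minus U87MG). The differences in log2 change were -4.65 for GDF15, -3.36 for MIR222HG, 1.84 for PID1, -2.15 for CDKN1A, -0.80 for TRA2A, and -5.66 for MARVELD2, whose U87MG controls held 12 to 18 counts. At 50 nM the effect differed for 6760 genes, by -4.92 for MARVELD2, whose U87MG controls held 6 to 7 counts, -1.04 for SLC20A1, -1.25 for GBP3, -1.08 for GGCX, 0.95 for PAWR, 0.36 for TRA2B and -0.70 for TRA2A. With siRNA it differed for 122 genes, by 1.11 for NPR3, 0.49 for ITSN1, 1.37 for SEPTIN4, 0.95 for MARCHF4, 0.60 for FARP2 and -0.50 for TRA2A. That count was 26 to 92 with 1 library left out, and it was under 122 by more than 1.5 times without any of the MDA-MB-231 libraries or U87MG controls, or without U87MG treated replicate 1. Among the gene lists, 1 that is not named differed between the lines by medians of -0.61 at 200 nM and -0.488 at 50 nM, and fibroblast markers differed by a median of 0.12 with siRNA (adjusted p = 0.0292 with an estimated correlation).

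The first pattern weighed is that the siRNA changed fewer genes than 200 nM ASO-1570 although it lowered TRA2B mRNA further. Lower depth of the siRNA libraries is argued against, since U87MG counts thinned to the depth of the 50 nM experiment still gave 11986 changed genes, and those of MDA-MB-231 gave 6364. A larger spread between siRNA replicates is argued against too, as the median SE of a log2 change in U87MG with siRNA was 0.573 times that with the oligonucleotide, and in MDA-MB-231 the median SEs were 0.054 and 0.095. Genes that 200 nM ASO-1570 changed at least 2-fold and that were tested with siRNA numbered 1287 in MDA-MB-231 and 3901 in U87MG. Their median siRNA change in the same direction was 0.056 in MDA-MB-231 (bootstrap 95% interval over genes 0.033 to 0.078, oligonucleotide median 1.414). In U87MG it was 0.048 (0.039 to 0.058, oligonucleotide median 1.503). These intervals resample genes as if they were independent and leave out the spread between libraries. With a mean log2 CPM of at least 3 the median siRNA change was 0.033 in MDA-MB-231 (181 genes) and 0.061 in U87MG (843 genes). These medians argue against loss of TRA2B mRNA as the whole cause of the oligonucleotide's changes. Effects of the oligonucleotide on other transcripts, effects of the TRA2B poison exon transcript and the separate experiments stay open as untested candidate explanations.

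The second pattern is that cassette exon inclusion fell more often than it rose in U87MG at 200 nM, in 79.8% of the changed cassette exon events. Among changed exons with a control PSI of 0.4 to 0.6, taken as 1 per gene, 45.9% fell (exact binomial 95% interval 42% to 49.8%, 649 exons), so a start near full inclusion, from which PSI can only fall, is a candidate explanation that this test left standing. In genes with a mean CPM of at least 50, 81.8% fell (80% to 83.4%, 1974 exons), so the excess of falls was not confined to genes with low counts. Few reads over the events cannot be judged from this. The depth of each event is unknown, and the starting PSI was not held fixed. Loss of TRA2B mRNA is argued against as the whole cause, though TRA2B protein was not measured. Of the 9573 cassette exon events that fell, 6054 had a value in every siRNA library. Their median siRNA change in PSI was -0.001 (bootstrap 95% interval over events -0.0013 to -0.0007), against -0.21 with the oligonucleotide. The interval treats events as independent, though some share an exon, and leaves out the spread between libraries. The 3193 events that also had a range of at least 0.05 with siRNA had a median of -0.0093.

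The third pattern is that fewer splicing events were called in MDA-MB-231 than in U87MG at 200 nM. Depth is argued against, since the median total count of MDA-MB-231 was 93.2% of that of U87MG. An uneven response may contribute. Over the cassette exon events changed in U87MG at 50 nM, the mean shift of the weakest treated MDA-MB-231 library was 61.7% of that of the strongest. It was 97.3% over the 74 events changed in MDA-MB-231 at 50 nM. Whether every treated MDA-MB-231 library responded less stays open. The strongest of them moved 54.2% as far as the weakest treated U87MG library over the exons chosen in U87MG and 110.2% as far over those chosen in MDA-MB-231, so the answer depends on the choice of exons. Differences between the lines in uptake or in splicing factors were not tested.

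For comparisons of 3 against 3 libraries there are 10 splits of the samples, too few for a share under 0.05. The real split gave 6601 changed genes against at most 1 in the others in MDA-MB-231 at 200 nM, 13003 against 1 in U87MG at 200 nM, 5590 against 3 and 13098 against 2 at 50 nM, and 1676 against 1 and 971 against 3 with siRNA. For splicing it gave 992 against 5 and 16057 against 3 events at 200 nM, 109 against 5 and 9229 against 3 at 50 nM, and 0 against 3 and 0 against 8 with siRNA. In each of these only 1 of 10 splits reached the real count, except for siRNA splicing, where 10 of 10 did. For differences between effects, fitted with the replicate block, the real split gave 4562 against 0 genes between the lines at 200 nM, 6728 against 0 at 50 nM and 110 against 5 with siRNA, 0 against 0 (10 of 10 splits) and 110 against 1 between doses in MDA-MB-231 and U87MG, and 2169 against 0 and 11576 against 0 between oligonucleotide and siRNA.

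In the PDX the real counts were 0 genes and 0 events, which any split reaches (100 of 100), so the splits say nothing about chance there, nor do they for the other counts of 0 above. The other splits of the tumours that called the most genes gave 9497, 7846 and 2259, and the rest gave at most 1. The split with 9497 set treated replicates 1 and 2 and control replicates 1, 3 and 4 against the others. Their mitochondrial counts were 17.65% to 38.06%, against 38.03% to 75.31% in the others. The highest shares were in treated tumours, so this grouping is not separate from the treatment. For splicing, 1 other split called 1402 events and the rest at most 2. What these splits reflect was not tested.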

How the results depend on the processing

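The alternatives chosen after seeing the data were thinning, the CPM minimum for splicing events, the joint siRNA splicing fit, the mitochondrial settings and PDX lists with tumours left out. Among 2666 values of named genes under the alternatives, 2629 kept their direction and side of the threshold, 31 were weaker, 1 was stronger and 5 were reversed. Among 1252 values of named splicing events, 979 kept theirs and 273 were weaker, so named events rest more on the processing than named genes. All 18 overlap tests, 80 of 81 values of the TRA2B poison exon and 78 of 82 of the TRA2A exon kept theirs, as did 70 of 84 counts of changed genes, 37 of 83 counts of changed events and 68 of 113 counts of differing genes, which stayed within 1.5 times. In the PDX, edgeR recovered 3% of simulated changes of log2 1, so results there are limited by the spread between tumours.

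Changed genes numbered 2638 and 1849 by DESeq2 and 982 and 481 without the low-count filter in MDA-MB-231 and U87MG with siRNA. With 1 library left out they ranged from 4221 to 7787 in MDA-MB-231 at 200 nM, 3696 to 5808 at 50 nM, 796 to 1408 with siRNA in MDA-MB-231 and 476 to 779 in U87MG. The cause was not tested, beyond the fewer samples in each of these fits.

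Genes whose change differed between the lines with siRNA numbered 509 by DESeq2, 80 with RLE size factors, 27 without the low-count filter and 26 to 92 with 1 library left out. Between doses they numbered 56 by DESeq2, 0 with the replicate block and 0 to 10 with 1 library left out in MDA-MB-231, and 893, 110 and 105 to 291 in U87MG, with 163 there without the low-count filter. Between oligonucleotide and siRNA in MDA-MB-231 they numbered 2415 without the filter, 2169 with the block and 2140 to 5629 with 1 library left out. The cause was not tested.

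Changed splicing events in MDA-MB-231 numbered 2362 on the logit scale, 400 without the range filter, 0 with the replicate block and 144 to 2452 with 1 library left out at 200 nM. At 50 nM they numbered 452, 41, 0 and 23 to 499, and 194 for genes with a mean CPM of at least 10. With the block, U87MG gave 10419 at 200 nM and 2885 at 50 nM, and 3575 to 11220 at 50 nM with 1 library left out. Replicate numbers were not taken to pair the MDA-MB-231 or PDX samples. A sample correlated best with its own number in 0 of 3 replicates at 200 nM, 1 at 50 nM and 1 with siRNA in MDA-MB-231. In the PDX it did so in 2 of 5. In U87MG it did so in all replicates except replicate 2 at 50 nM and replicate 3 with siRNA. With siRNA, events numbered 29 in MDA-MB-231 and 53 in U87MG with at least 2 values per group, 4 and 1 without the range filter, 6 on the logit scale in U87MG, 3 to 11 and 3 to 12 with 1 library left out, and 315 in the joint fit. The PDX gave 7 with at least 2 values per group and 0 to 1 with 1 tumour left out. The cause was not tested.

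No list was called with an estimated correlation in any of the 7 comparisons (0 in each, against 13, 8, 12, 10, 4, 3 and 11), and 2 were called in the PDX without the libraries over 50% mitochondrial counts. With an estimated correlation, 0 were called in the PDX with those libraries or any 1 tumour left out. With the replicate block, interferon response was also called in MDA-MB-231 at 200 nM (adjusted p = 0.0379, against 0.55 with an estimated correlation), heat shock proteins at 50 nM (0.0236 against 0.788) and endoplasmic reticulum chaperones with siRNA (0.000442 against 0.894). Fibroblast markers were lost at 200 nM (0.303 against 0.55) and 50 nM (0.157 against 0.552).

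Signs reversed for values that were not called. With 1 library left out, TRA2A in the PDX ranged from -0.181 to 0.043, the TRA2B difference between doses in MDA-MB-231 from -0.138 to 0.015 and that of TRA2A from -0.011 to 0.065, and the poison exon difference in MDA-MB-231 with siRNA from -0.027 to 0.079.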

Other observations

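The classes of noncoding and read-through genes below, and their counts, were chosen after the data were seen, and no explanation was tested for them.

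Among long noncoding RNAs more rose than fell with ASO-1570, while among protein-coding genes more fell than rose; the difference was not tested, and most long noncoding RNAs in MDA-MB-231 were not called. In U87MG at 200 nM, 45.1% of 1137 long noncoding RNAs rose and 19.6% fell, against 21.3% and 41.9% of 12014 protein-coding genes. At 50 nM 38.3% of 1523 rose and 19.1% fell, against 25.6% and 41.9% of 12060. In MDA-MB-231 at 200 nM 24.9% of 882 rose and 12.2% fell, against 12.8% and 24.5% of 12028 protein-coding genes, and at 50 nM 16% of 1284 rose and 10% fell, against 11.3% and 22.9% of 12045. Host genes of microRNAs rose in 16 of 23 cases and fell in 5 in U87MG at 200 nM, and divergent transcripts (symbols ending in DT) rose in 80 of 147 and fell in 20. At 50 nM in U87MG the hosts rose in 18 of 25 and fell in 4, and divergent transcripts rose in 78 of 158 and fell in 23. In MDA-MB-231 the hosts rose in 10 of 20 and fell in 4 at 200 nM and rose in 7 of 24 and fell in 4 at 50 nM, and divergent transcripts rose in 32 of 91 and 26 of 109 and fell in 8 and 7. With siRNA more divergent transcripts fell than rose, at 7 and 2 of 97 in MDA-MB-231 and 5 and 2 of 130 in U87MG, and hosts rose in 2 and fell in 1 of 23 and rose in 1 and fell in 1 of 24. With siRNA, 2.9% of 1424 long noncoding RNAs rose and 1.5% fell in U87MG, against 2.3% and 4.6% of 12119 protein-coding genes, and 3.5% of 1264 rose and 3% fell in MDA-MB-231, against 5.8% and 6.2% of 12052.

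Read-through genes, whose symbol joins those of other genes, varied more between libraries of a group than other genes did. STBD1, which overlaps such a gene, was counted with the other genes. Counts of STBD1 in treated MDA-MB-231 libraries at 50 nM ran from 3.02 to 28.7 CPM while the sum with its read-through partner ran from 28.8 to 34.4 CPM. In U87MG at 50 nM, STBD1 stood at 3.44 to 4.08 CPM in control and 25.8 to 28.2 CPM in treated libraries, and the sums at 27 to 28.6 and 26.4 to 28.7 CPM. The median SD of log2 CPM within groups was 0.378, 0.635 and 0.599 for read-through genes in the 200 nM, 50 nM and siRNA experiments, against 0.131, 0.102 and 0.077 for other genes. At 200 nM these medians cover 56 read-through and 13019 other genes, a part of the genes tested.

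In the cell lines, each library's counts correlated best with the PSI column of its own number within its group, in 12 of 12 libraries of each table. Over all libraries of a table, the best match lay in the own group in 12 of 12 libraries at 200 nM and at 50 nM and in 11 of 12 with siRNA. In the PDX 1 of 10 libraries matched its own number, while 10 of 10 matched best within their own group, so count and PSI columns of the PDX were not joined library by library. Mean PSI of retained introns was 0.449 to 0.553 per library in the PDX and 0.353 to 0.403 in the lines.

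Of genes that fell in MDA-MB-231 at 200 nM and were tested in the PDX, 68.5% (2254 of 3289) had the same sign in the PDX, as did 54.1% (1380 of 2550) of those that rose. Of all 20190 genes tested in both, 52.5% were lower and 47.5% higher in treated tumours. No gene was called in the PDX, and genes are not independent of each other, so no test was made on these shares.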
